A study of Mus musculus with 6 samples.

How the data were processed

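The counts analysed were the UMI counts the authors deposited, 1 table of 27998 genes and 21685 cells, with 8608 genes without a count. Per the submitters' processing notes, reads were processed with bcl2fastq 2.17.1.14 and Cell Ranger 2.0.1 on mm10, followed by Seurat 2.3.0 and limma 3.32.10, and the cell selection behind the table is not given in the sources used here. The libraries were 3' v2 droplet libraries. Cells were mapped to the 6 mice by the labels in the table. The groups, tests, gene lists, marker sets, alternatives and naming rule were chosen before the data were examined, except where stated below.

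Cells with 500 or more genes and at most 20% mitochondrial UMIs were kept, which left 21658 cells and removed 27. Doublets were scored per mouse with the scrublet implementation of scanpy. Its automatic threshold marked 45 cells (0.208%), so after this was seen the threshold was set at the expected rate of 0.8% per 1000 cells, and the 634 cells so called (2.93%) were removed, leaving 21024. The numbers called were 134, 65, 132, 115, 94 and 94 in mice 654, 657, 670, 671, 698 and 699. The smallest UMI count of a cell differed between the libraries (1006, 1985, 929, 1482, 1541 and 1893). Log-normalised values of 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 gave 23 clusters, with no integration of mice. Mitochondrial, Xist and Y-linked genes were left out of the variable genes. A cluster took the name of the marker set with the highest mean log2 fold among sets with at least 3 markers detected in 5% of its cells at a fold of 1.5 or more over other cells (5 CPM added). It stayed unnamed where its 10 genes with the highest fold held more markers of another set than of that one, or held none of that one at a median depth under 0.333 of its mouse, and was called an unnamed neuron cluster with 10 or more pan-neuronal markers in 25% of its cells. Pan-neuronal and proliferating sets gave no names. This rule was set after the clusters were seen, and the 20 marker sets were fixed before.

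UMI counts were summed per mouse over neurons (3837, 2766, 3740, 3544, 3232 and 3288 cells; 13138352, 17658500, 11821486, 15885425, 16717042 and 18533754 UMIs) and over each class with 20 or more cells in every mouse. Each mouse was 1 replicate. edgeR (TMM, filterByExpr, quasi-likelihood F test) was fitted to raw counts of all 6 mice with 1 mean per group, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation in neurons was 12.3%. Age, basal diet and any strain difference go with genotype and could not be fitted. The count over classes is the sum of the calls in the 7 classes, a choice made after the data were seen, as was testing the unnamed clusters 9 and 18. The interaction of NF-like neurons with group used mouse as a block. The 20 gene lists were tested with camera on voom values with a preset correlation of 0.01, with an estimated correlation and with fry. Shares were compared by exact permutation. Called genes were fitted again with each class thinned to the smallest UMI sum of a mouse, in 1 draw and, added after results were seen, in 20 draws. Positions are mm10 coordinates, in full on the chromosome of Ttpa.

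Genes were named by a fixed rule: per contrast, up to 10 genes per direction in neurons and up to 5 in a class with the largest fold change among those with adjusted p under 0.05, average log2 CPM of 4 or more and both mice of 1 group above both of the other. Where fewer than 5 passed, the 5 with the smallest p were named as not passing. For each list up to 2 members per direction with the smallest p were named. Other calls named in the text fall outside this rule and were added so that calls in NP1-like and NP2-like neurons are given; these were not followed through the alternatives. Results for some genes are not reported here, and these were not followed through the alternatives, while counts of calls and list statistics include them. List medians and counts are of voom values, and values of members are of the edgeR fit. Ratios from 1 to 3 counts carry a counting interval, and 0 counts take a floor of 3.

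Alternatives chosen before were RLE size factors, no low-count filter, DESeq2, limma-voom, sex as a term, each mouse left out, doublets kept, a stricter filter (1000 genes, 10% mitochondrial), all cells, thinning to the smallest library, a matched class mix and Leiden resolutions of 0.5 and 2. The stricter filter, all cells, the matched mix and other resolutions were not run for genes in classes. Added after the data were seen were both Ttpa-/- diets against wild type and leaving out the shallowest library of each Ttpa-/- group. At first only list members with an unadjusted p under 0.05 were followed, a narrowing chosen after results were seen and removed.

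In a self-test, 50 genes each were changed by 1.5, 2, 4 and 8 times in simulated neuron counts over 13205 genes. edgeR recovered 21, 49, 50 and 50 with 14 unchanged genes called, DESeq2 26, 49, 50 and 50 with 8, and limma-voom 24, 49, 50 and 50 with 13. With nothing changed edgeR made 1 call. Wdfy1 in real deficient neurons, at 3.47 times wild type, did not pass. For the interaction (10106 genes) edgeR recovered 5, 23, 50 and 50 with 6 unchanged genes called and DESeq2 3, 20, 47 and 50 with 3. With the cholesterol list raised by 1.5 times, only it was called, also with the estimated correlation (adjusted p = 0.00933). Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.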

Results

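Single-cell RNA profiles of dorsal root ganglion neurons were compared between 3 groups of 2 mice: wild type mice on a basal diet, Ttpa-/- mice whose diet lacked vitamin E (deficient) and Ttpa-/- mice given added vitamin E (supplemented). Ttpa encodes the alpha-tocopherol transfer protein, which retains vitamin E in the body. Each group held 1 female and 1 male mouse, aged 5 months in wild type and 6 months in Ttpa-/- mice. Mice are named here by the numbers in their labels: 654 and 657 had the deficient diet, 670 and 671 the supplemented diet, and 698 and 699 were wild type. The deposited table held counts of unique molecular identifiers (UMIs) for 27998 genes in 21685 cells. The libraries held 13867799, 18203134, 12538785, 16723463, 17501964 and 19383933 UMIs in mice 654, 657, 670, 671, 698 and 699, with median UMIs per cell of 2856, 4959, 2499.5, 3478, 4037 and 4350. After filters and removal of doublets, 3958, 2791, 3934, 3671, 3331 and 3339 cells were kept.

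Ttpa (mm10, chromosome 4, 20007938 to 20030785) was almost absent from every library, with 4 UMIs in mouse 654, 5 in 657, 1 in 670, 4 in 671 and 0 in each of the wild type mice 698 and 699. These correspond to 0.299, 0.282, 0.0824 and 0.248 UMIs scaled to library size (counts per 1e6, CPM) in the Ttpa-/- mice, with 95% counting intervals of 0.0816 to 0.767, 0.0916 to 0.659, 0.00209 to 0.459 and 0.0675 to 0.634. In the wild type mice a floor of 3 counts would be 0.177 and 0.161 CPM. The labels do not give the deleted part of the gene, and reads at the 3' end outside it check nothing about the deletion, so genotype names are those of the labels throughout. Sex-linked genes matched the labelled sex in 6 of 6 mice. Xist, expressed from the inactive X chromosome, had 10597, 15705 and 13837 UMIs in the females 654, 671 and 698 and 5, 1 and 4 in the males 657, 670 and 699. The Y-linked gene Ddx3y had 1453, 869 and 1350 UMIs in those males and 0, 0 and 1 in those females.

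The cells formed 23 clusters, 20 of them assigned by fixed marker sets to neuron classes or unnamed neuron clusters and 3 to non-neuronal classes. Peptidergic (PEP-like) nociceptors made up 5 clusters, large myelinated (NF-like) neurons 4, Mrgprd-type non-peptidergic (NP1-like) nociceptors 3 and Th-type C-fibre mechanoreceptors (TH-like) 3. NP2-like neurons, Sst and Nppb (NP3-like) itch neurons, TRPM8-like cold neurons, satellite-glia-like, macrophage-like and endothelial-like cells had 1 cluster each. Cluster 9, led by Mrgpra3, had 2 NP2-like (itch) markers, too few for a name. The NP2-like cluster had 3, none in its 10 leading genes, so its type is open. Cluster 18 carried neuronal genes and 3 markers each of non-myelinating Schwann-like and satellite-glia-like cells, but its leading genes held the fibroblast-like marker Dcn and none of those, so it was left unnamed. Among TH-like cells, cluster 0 held the most in mice 657, 671 and 699 and cluster 7 held the most in mice 654, 670 and 698. Gene tests were run in 7 classes with 20 or more cells in every mouse. TRPM8-like, endothelial-like and macrophage-like cells had as few as 19, 3 and 1 cells in a mouse and were not compared.

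In deficient against wild type mice, Wdfy1 rose in 4 neuron classes, Necab1 rose and Car8 fell in NP3-like neurons, Car8 fell in PEP-like neurons, and alpha and beta globin transcripts rose in PEP-like neurons. With edgeR quasi-likelihood tests and Benjamini-Hochberg adjustment within each class, 18 calls were made in 6 of the 7 classes, 16 higher and 2 lower, in 14 distinct genes. DESeq2 made 11 calls and limma-voom 15. Values below are log2 fold change ± standard error with n = 2 mice per group. With 2 mice per group each p-value rests on a spread shared across groups and genes, and the counting intervals cover counting error only. Wdfy1 (chromosome 1), which encodes an early endosome protein with a phosphoinositide-binding domain, was higher in NF-like (2.16 ± 0.30, adjusted p = 0.00390; 29.0 and 72.7 against 11.6 and 12.1 CPM), NP1-like (1.67 ± 0.24, adjusted p = 0.0104), NP3-like (1.68 ± 0.29, adjusted p = 0.00882) and PEP-like neurons (1.90 ± 0.21, adjusted p = 3.23e-05). The Wdfy1 call ended in NF-like neurons when 1 mouse was left out (adjusted p = 0.301 without 657, 0.290 without 698 and 0.897 without 699; also with DESeq2), in NP1-like neurons (0.324 without 698 and 0.141 without 699) and in NP3-like neurons (1 without 657 and 0.0899 without 699; also with DESeq2). In PEP-like neurons it held under all 14 alternatives run for classes.

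Necab1 (chromosome 4, 14952245 to 15149794), a neuronal EF-hand calcium-binding protein gene, was higher in NP3-like neurons of deficient mice (3.34 ± 0.38, adjusted p = 1.44e-05; 97 against 9 UMIs; 37.5 and 44.8 against 2.91 and 4.75 CPM), and the call held under those 14 alternatives. Car8 (chromosome 4, 8143362 to 8239041) encodes a carbonic anhydrase-related protein that binds the type 1 inositol trisphosphate receptor. Car8 was lower in NP3-like neurons (-6.61 ± 0.79, adjusted p = 1.96e-05; 2 against 213 UMIs, a wild type to deficient ratio of 108 with a counting interval of 29.4 to 894) and in PEP-like neurons (-6.41 ± 0.95, adjusted p = 0.00184; 4 against 475 UMIs). The Car8 call ended in NP3-like neurons without mouse 654 (adjusted p = 0.0965) and with DESeq2, and in PEP-like neurons without 698 (adjusted p = 0.0604), with DESeq2 and with limma-voom. Necab1 and Car8 lie 4.86 and 11.8 Mb from Ttpa on the same chromosome. Hba-a1 (chromosome 11; 3.77 ± 0.38, adjusted p = 1.20e-05), Hbb-bs (chromosome 7; 3.78 ± 0.39, adjusted p = 1.20e-05; 43.8 and 82.4 against 7.19 and 2.45 CPM) and Hba-a2 (chromosome 11; 1.83 ± 0.26, adjusted p = 0.00128), which encode globin chains, were higher in PEP-like neurons. Hbb-bt (chromosome 7) had 90 against 1 UMIs, a ratio of 124 with a counting interval of 21.6 to 4939. The globin pairs are near-identical, so the copy read is uncertain. All neurons, PEP-like included, had 4 of 4 erythroid-like markers higher (median 1.98). No globin gene was called in another class in these contrasts. In other classes but NP2-like, Hbb-bs was highest in 654 or 670 (TH-like: 79, 1, 163, 1, 4 and 3 UMIs in mouse order). In NP2-like neurons Hba-a1 went the other way. It was called with both diets as 1 group, chosen after results were seen (-4.46 ± 0.87, adjusted p = 0.0147). Wild type 699 held 114 of these 128 Hba-a1 UMIs. Background RNA was not measured. Hba-a2 lost its call without mouse 698 (adjusted p = 0.0604) and with doublets kept. Gm10600 (chromosome 4, 42240639 to 42242685), a predicted gene 22.2 Mb from Ttpa, was higher in PEP-like neurons (1.52 ± 0.28, adjusted p = 0.0265), a call that ended when 1 mouse was left out (adjusted p = 1 without 654, 0.0501 without 670, 0.0554 without 671, 0.474 without 698 and 0.188 without 699; also with DESeq2, with limma-voom, without the shallowest libraries).

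In NP2-like neurons 5 genes were higher in deficient than in wild type mice. Pam (chromosome 1; 1.11 ± 0.19, adjusted p = 0.00938) encodes the enzyme that amidates neuropeptides. Tmf1 (chromosome 6; 1.20 ± 0.24) encodes a Golgi-associated protein, Rbm15 (chromosome 3; 1.97 ± 0.40) an RNA-binding protein of the m6A writer complex, Bhlhe41 (chromosome 6; 0.91 ± 0.19) a repressor of clock genes and Actb (chromosome 5; 0.84 ± 0.17) beta-actin, each with an adjusted p of 0.0482. All 5 calls ended when 1 mouse was left out: Pam (adjusted p = 0.224 without 657, 0.167 without 698 and 0.196 without 699), Tmf1 (0.665 without 654, 0.549 without 698 and 0.592 without 699; also with DESeq2, with sex, with doublets kept, without the shallowest libraries, with both diets as 1 group), Rbm15 (0.384 without 657, 0.0583 without 698 and 0.820 without 699; also with DESeq2, with limma-voom, with sex, with doublets kept), Bhlhe41 (0.306 without 654, 0.224 without 657, 0.0583 without 698 and 0.858 without 699; also with sex, with doublets kept, without the shallowest libraries) and Actb (0.416 without 654, 0.384 without 657, 0.320 without 698 and 0.420 without 699; also with sex, with doublets kept, without the shallowest libraries). In 1 draw of UMI sums thinned to the smallest, all 5 also ended (adjusted p = 0.0946 for Pam, 0.222 for Tmf1, 0.995 for Rbm15, 0.0946 for Bhlhe41 and 0.0946 for Actb). Over 20 such draws they were called in 0 (Rbm15) to 11 (Pam), with a median Rbm15 fold of 1.80 (log2). The class total fell to 11 calls without wild type mouse 699 and stood at 43 without 657, 39 without 670 and 30 without 671.

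**Figure D1:**
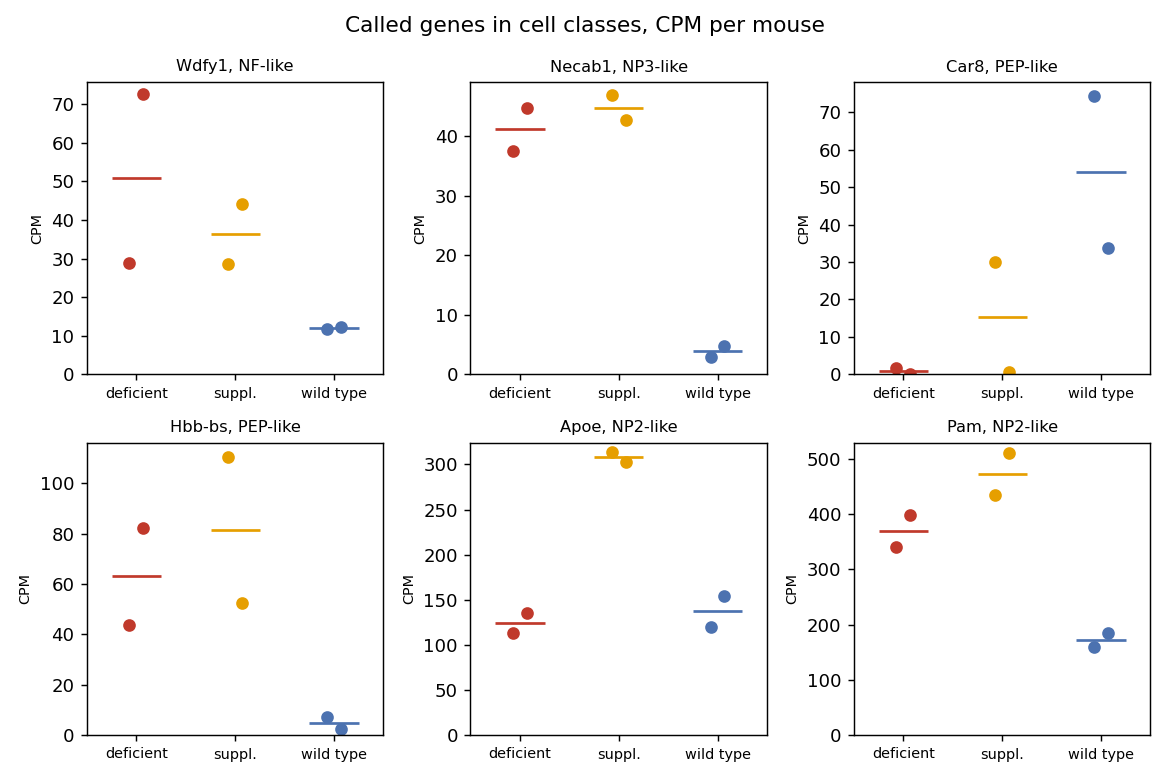
CPM per mouse for 6 genes called in cell classes. Dots are mice and lines are group means.

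Genes with the smallest p that did not pass in deficient against wild type mice were, in NF-like neurons, D17H6S53E (1.36 ± 0.28, adjusted p = 0.435), Pam (0.77 ± 0.18), Abhd2 (0.74 ± 0.18, adjusted p = 0.863) and Calb1 (-0.71 ± 0.18). In NP1-like neurons they were Hbb-bs (4.16 ± 0.78), Gnb1 (0.56 ± 0.11), Gm7271 (-0.88 ± 0.17) and Alcam (-0.73 ± 0.14, adjusted p = 0.112), and in NP3-like neurons Asph (1.22 ± 0.29, adjusted p = 0.431) and Pcna (-1.30 ± 0.36). In satellite-glia-like cells they were Cartpt (-1.43 ± 0.35, adjusted p = 0.132), Cryab (1.42 ± 0.42), Mbp (1.53 ± 0.45) and Fxyd1 (1.27 ± 0.38, adjusted p = 0.856). TH-like neurons had 0 calls with edgeR, DESeq2 and limma-voom and 193 genes with an unadjusted p under 0.05 with edgeR, but 2 calls without 654 and 11 without 657. Among the smallest p there were those of Wdfy1 (1.48 ± 0.32), Sdc4 (2.12 ± 0.46, adjusted p = 0.939), Timmdc1 (1.18 ± 0.28) and Banp (-1.39 ± 0.35). In the unnamed neuron cluster 9, Car8 was lower (-2.97 ± 0.41, adjusted p = 0.00149) and Wdfy1 (2.14 ± 0.37, adjusted p = 0.0218) and Ppp1r1a (1.05 ± 0.19, adjusted p = 0.0336), which encodes a protein phosphatase 1 inhibitor, were higher.

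Summed over all neurons, no gene of 13333 passed in deficient against wild type mice with edgeR (516 with an unadjusted p under 0.05, against 667 expected by chance) or limma-voom, and DESeq2 called 2. The smallest p belonged to Wdfy1 (1.79 ± 0.25, adjusted p = 0.133), Car8 (-4.42 ± 0.76, adjusted p = 0.451), Gm10600 (1.27 ± 0.22), Rpgrip1 (0.78 ± 0.14), a gene of the photoreceptor connecting cilium, and the zinc transporter gene Slc39a1 (1.0 ± 0.20, adjusted p = 0.863). 1 gene passed without each of mice 654, 657, 670 and 671. The Car8 values were 15 and 27 UMIs in the deficient mice, 197 in 670, 22 in 671 and 593 and 430 in the wild type mice, or 1.138, 1.56, 16.3, 1.38, 35.9 and 23.3 CPM. NP1-like markers stood higher in deficient neurons (9 of 9 higher, median 0.52) and NF-like markers lower (0 of 16 higher, median -0.37). The other marker sets were PEP-like (2 of 11 higher, median -0.19), NP2-like (4 of 5 higher, median 0.12), NP3-like (7 of 8 higher, median 0.23), TH-like (2 of 8 higher, median -0.080), TRPM8-like (2 of 4 higher, median 0.025) and pan-neuronal (4 of 13 higher, median -0.025). Markers of other cell types were satellite-glia-like (8 of 10 higher, median 0.040), myelinating Schwann-like (7 of 8 higher, median 0.49) and non-myelinating Schwann-like (3 of 8 higher, median -0.036). Fibroblast-like (5 of 7 higher, median 0.96), endothelial-like (5 of 7 higher, median 0.37), mural-like (4 of 4 higher, median 0.91), macrophage-like (2 of 4 higher, median 0.058) and proliferating (0 of 4 higher, median -0.15) markers were also measured.

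Of the 20 gene lists, 6 passed in deficient against wild type neurons with camera at a preset correlation of 0.01, and 0 with an estimated correlation (adjusted p = 0.804 for 5 of the 6 and 0.826 for the ribosomal list) or with fry. At the preset correlation mitochondrially encoded genes, which encode subunits of the respiratory chain, tested lower (median -0.37, 0 of 13 higher, adjusted p = 1.24e-09). Their members with the smallest p were mt-Atp8 (-0.59 ± 0.21) and mt-Nd3 (-0.45 ± 0.16), neither of which passed. Median mitochondrial shares were 2.66% and 4.11% in the deficient libraries against 4.80% and 3.97% in wild type. Cholesterol synthesis and SREBP targets tested higher (median 0.13, 22 of 25 higher, adjusted p = 6.31e-04). The members with the smallest p in each direction were Insig1 (0.34 ± 0.14), Mvd (0.30 ± 0.15), Hsd17b7 (-0.099 ± 0.14) and Cyp51 (-0.084 ± 0.14). The myelin list tested higher (median 0.26, 9 of 11 higher, adjusted p = 0.00346) beside the myelinating Schwann-like markers (7 of 8 higher, median 0.49), with Mal (0.70 ± 0.22), Ugt8a (1.56 ± 0.54), Egr2 (-0.013 ± 0.38) and Pllp (-0.15 ± 0.30) as the members with the smallest p. The inflammation and interferon list tested higher (median 0.21, 16 of 20 higher, adjusted p = 0.0142), with Cxcl1 (0.67 ± 0.35), Il6 (-0.33 ± 0.44) and Ccl2 (-0.16 ± 0.17). Immediate early genes, which respond to handling and dissociation, tested lower (median -0.093, 7 of 22 higher, adjusted p = 0.0123), with Atf3 (0.092 ± 0.13), Nr4a1 (0.20 ± 0.23), Ier5 (-0.57 ± 0.23) and Nr4a2 (-0.52 ± 0.23). Cytosolic ribosomal protein genes tested lower (median -0.060, 12 of 50 higher, adjusted p = 0.0142), with Rps9 (0.11 ± 0.13), Rpl3 (0.13 ± 0.14), Rps24 (-0.31 ± 0.17) and Rps25 (-0.22 ± 0.15). Counts of lists were 3 without mouse 654, 10 without 698 and 1 without 699. The inflammation and ribosomal tests turned direction without 699. Adjusted over the list alone, 2 members passed with edgeR. They were Sdc1 of the axon injury list and Mrgprd of the neuropeptide list.

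The other 14 lists did not pass in deficient against wild type neurons, and their members are given as values. The vitamin E transport list had 9 of 15 members higher (median 0.023, adjusted p = 0.978; test direction lower). Scarb1 (0.27 ± 0.28), Npc1 (0.20 ± 0.19), Lpl (-0.52 ± 0.24) and Abcg1 (-0.25 ± 0.16) had its smallest p in each direction. The antioxidant and NRF2 target list had 19 of 33 members higher (median 0.021, adjusted p = 0.761). Ftl1 (0.23 ± 0.12), Hmox1 (0.49 ± 0.16), Gstm1 (-0.36 ± 0.15) and Mgst1 (-0.49 ± 0.18) had its smallest p in each direction. The lipid peroxidation list had 12 of 20 members higher (median 0.063, adjusted p = 0.176). Lpcat3 (0.32 ± 0.17), Aifm2 (0.77 ± 0.42), Acsl4 (-0.093 ± 0.12) and Elovl5 (-0.16 ± 0.14) had its smallest p in each direction. The LXR and RORA target list had 8 of 17 members higher (median -0.0078, adjusted p = 0.579). Lpcat3 (0.32 ± 0.17), Nr1d2 (-0.46 ± 0.19) and Pcp4 (-0.79 ± 0.23) were among the members with its smallest p in each direction. The nuclear oxidative phosphorylation list had 31 of 74 members higher (median -0.0085, adjusted p = 0.337). Ndufa9 (0.20 ± 0.16), Ndufv1 (0.14 ± 0.13), Atp5e (-0.23 ± 0.13) and Atp5j2 (-0.19 ± 0.13) had its smallest p in each direction. The heat shock list had 4 of 15 members higher (median -0.093, adjusted p = 0.239). Hspa4 (0.12 ± 0.13), Hspa1a (0.18 ± 0.20), Hspb1 (-0.30 ± 0.17) and Hspa1b (-0.29 ± 0.17) had its smallest p in each direction. The endoplasmic reticulum stress list had 14 of 23 members higher (median 0.084, adjusted p = 0.587). Sesn2 (0.61 ± 0.33), Atf5 (0.21 ± 0.14), Pdia4 (-0.24 ± 0.19) and Dnajb9 (-0.26 ± 0.15) had its smallest p in each direction.

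Lists of excitability, release and axons in deficient against wild type neurons were as follows. The sodium and calcium channel list had 13 of 26 members higher (median -0.0023, adjusted p = 0.587). Scn2b (0.19 ± 0.13), Scn11a (0.31 ± 0.21), Cacna1e (-0.67 ± 0.21) and Scn1a (-0.59 ± 0.26) had its smallest p in each direction. The potassium channel list had 16 of 39 members higher (median -0.12, adjusted p = 0.108). Kcnip4 (0.30 ± 0.17), Kcnip2 (0.40 ± 0.14), Kcnk1 (-0.41 ± 0.17) and Kcnq3 (-0.51 ± 0.19) had its smallest p in each direction. The synaptic release list had 11 of 38 members higher (median -0.067, adjusted p = 0.106). Unc13c (0.21 ± 0.15), Syt7 (0.34 ± 0.13), Snap25 (-0.33 ± 0.17) and Sv2b (-0.55 ± 0.25) had its smallest p in each direction. The mechanotransduction list had 6 of 14 members higher (median -0.0073, adjusted p = 0.718; test direction higher). Trpc6 (0.81 ± 0.31), Kcnk2 (-0.26 ± 0.16) and Asic3 (-0.47 ± 0.32) were among the members with its smallest p in each direction. The neuropeptide and receptor list had 15 of 23 members higher (median 0.11, adjusted p = 0.587). Mrgprd (1.0 ± 0.25), Gfra2 (0.35 ± 0.16), Ntrk2 (-0.38 ± 0.15) and Gal (-0.30 ± 0.11) had its smallest p in each direction. The axon injury list had 11 of 20 members higher (median 0.044, adjusted p = 0.783). Plaur (0.80 ± 0.26), Sdc1 (0.84 ± 0.22), Stmn4 (-0.45 ± 0.16) and Gal (-0.30 ± 0.11) had its smallest p in each direction. The cytoskeleton list had 18 of 37 members higher (median -0.012, adjusted p = 0.633). Tubb2b (0.32 ± 0.13), Prph (0.22 ± 0.13), Map2 (-0.37 ± 0.17) and Stmn4 (-0.45 ± 0.16) had its smallest p in each direction.

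Between the diets, Apoe and Fabp7 were lower in NP2-like neurons of deficient than of supplemented mice, and Apoe was lower in NP1-like neurons. These were the 3 calls of edgeR over 7 classes, in 2 distinct genes, beside 2 with DESeq2 and 3 with limma-voom. Apoe (chromosome 7), which encodes a lipoprotein component made mostly by glia in nervous tissue, differed in NP2-like (-1.29 ± 0.19, adjusted p = 9.91e-04; 113 and 135 against 314 and 303 CPM) and NP1-like neurons (-1.03 ± 0.15, adjusted p = 0.00680; 111 and 98.7 against 178 and 252 CPM). Fabp7 (chromosome 10), the fatty acid binding protein of satellite glia, differed in NP2-like neurons (-1.71 ± 0.27, adjusted p = 9.91e-04). Satellite-glia-like markers in all neurons moved the same way (0 of 10 higher, median -0.75). Apoe in NP1-like neurons lost its call when 1 mouse was left out (adjusted p = 0.108 without 657 and 0.468 without 671), as did Fabp7 in NP2-like neurons (0.519 without 657 and 0.607 without 671; also with DESeq2). Apoe in NP2-like neurons lost its call without the shallowest libraries (adjusted p = 0.0768). Without mouse 654, 657, 670, 671, 698 or 699 the class total was 19, 6, 14, 18, 17 and 15. In the unnamed cluster 18, Fabp7 (-1.73, adjusted p = 0.0203; 181 and 190 against 252 and 923 CPM) and Apoe (-1.59, adjusted p = 0.0203; 544 and 369 against 504 and 2128 CPM) were also lower in group means, mainly through mouse 671, and Apoe in 670 was below that in 654.

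TH-like, NF-like, NP3-like, PEP-like and satellite-glia-like cells had 0 calls between the diets with edgeR, DESeq2 and limma-voom, with 218, 314, 236, 310 and 96 genes at an unadjusted p under 0.05 with edgeR. These counts rose to 6 in TH-like (without 654), 5 in NF-like (without 670 or 671), 8, 12 and 10 in NP3-like (without 671, 698 and 699), 3 in PEP-like (without 654) and 3 in satellite-glia-like cells (without 654 or 671). Smallest p values that did not pass were, in NF-like neurons, Zfp36 (-0.98 ± 0.25), Tfrc (0.58 ± 0.16), Rufy1 (-1.41 ± 0.38), C1qtnf1 (-1.18 ± 0.32) and Ogfod3 (1.19 ± 0.33). In NP1-like neurons they were Fabp7 (-0.94 ± 0.17, adjusted p = 0.111), Cartpt (0.86 ± 0.19), Nrg2 (-1.87 ± 0.46) and Rdh13 (-1.76 ± 0.43), and in NP2-like neurons Rsrp1 (-0.77 ± 0.20), Fxr1 (-0.83 ± 0.23) and Dnajb4 (-1.07 ± 0.30). In NP3-like neurons they were Fxyd1 (-1.61 ± 0.33), Apoe (-0.81 ± 0.17, adjusted p = 0.188), Plaur (1.11 ± 0.27), Dbi (-0.80 ± 0.19) and Ifitm1 (1.53 ± 0.38). In PEP-like neurons they were Ccl4 (2 against 28 UMIs, a supplemented to deficient ratio of 14.9 with a counting interval of 3.77 to 129), Gpm6b (-0.78 ± 0.18), Iigp1 (1.61 ± 0.38), Id3 (-0.83 ± 0.21) and Ccl2 (0.73 ± 0.19). Satellite-glia-like cells had Alcam (-1.68 ± 0.42, adjusted p = 0.458), Malat1 (-0.76 ± 0.21), Chmp2a (-1.71 ± 0.49), Ccl2 (1.136 ± 0.35) and Tomm20 (0.94 ± 0.29), and TH-like neurons Adamts5 (-1.71 ± 0.46), Pik3r1 (-0.81 ± 0.22), Tpst2 (1.09 ± 0.30), Ptn (-0.69 ± 0.19) and Ttyh1 (-1.97 ± 0.56).

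Summed over all neurons, edgeR, DESeq2 and limma-voom called 0 genes between the diets (308 with an unadjusted p under 0.05 with edgeR, against 667 expected by chance). Among the smallest p were those of the chemokine gene Ccl4 (-3.21 ± 0.64), Ttyh1 (-1.10 ± 0.25), Notch1 (-1.43 ± 0.34) and the glial glutamate transporter gene Slc1a3 (-1.30 ± 0.31), each with an adjusted p of 0.999. 1 gene passed without mouse 671. Other marker sets were myelinating Schwann-like (4 of 8 higher, median -0.071), non-myelinating Schwann-like (0 of 8 higher, median -0.21) and erythroid-like (0 of 4 higher, median -0.60). Fibroblast-like (1 of 7 higher, median -0.43), endothelial-like (4 of 7 higher, median 0.038), mural-like (2 of 4 higher, median -0.056), macrophage-like (1 of 4 higher, median -0.36) and proliferating (2 of 4 higher, median -0.10) markers were also measured. Neuron sets were NP1-like (8 of 9 higher, median 0.034), NF-like (3 of 16 higher, median -0.31), PEP-like (7 of 11 higher, median 0.049), NP2-like (5 of 5 higher, median 0.20), NP3-like (8 of 8 higher, median 0.33), TH-like (4 of 8 higher, median 0.013), TRPM8-like (2 of 4 higher, median -0.052) and pan-neuronal (8 of 13 higher, median 0.039).

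Of the 20 lists, 1 passed between the diets. The immediate early list tested lower in deficient neurons (median -0.19, 4 of 22 higher, adjusted p = 2.17e-04), with an adjusted p of 0.527 with an estimated correlation. The members with the smallest p in each direction were Jund (0.042 ± 0.15), Ier3 (0.21 ± 0.13), Nr4a3 (-0.68 ± 0.28) and Zfp36 (-0.41 ± 0.17). Without mouse 654 the count was 3, without 671 it was 4, and without 657 or 670 it was 2. Adjusted over the list alone, 3 members passed: Apoe in the vitamin E and the LXR lists and Ccl4 in the inflammation list. The vitamin E transport list had 4 of 15 members higher (median -0.16, adjusted p = 0.0965). Ttpal (0.087 ± 0.14), Pltp (0.48 ± 0.22), Apoe (-0.79 ± 0.19) and Abcg1 (-0.33 ± 0.16) had its smallest p in each direction. The antioxidant and NRF2 target list had 22 of 33 members higher (median 0.070, adjusted p = 0.264). Prdx6 (0.23 ± 0.13), Ftl1 (0.20 ± 0.12), Sod3 (-0.73 ± 0.52) and Mgst1 (-0.39 ± 0.18) had its smallest p in each direction. The lipid peroxidation list had 13 of 20 members higher (median 0.070, adjusted p = 0.281). Lpcat3 (0.37 ± 0.18), Tfrc (0.41 ± 0.13), Acsl4 (-0.20 ± 0.13) and Elovl2 (-0.65 ± 0.36) had its smallest p in each direction. The cholesterol synthesis list had 15 of 25 members higher (median 0.040, adjusted p = 0.531). Mvd (0.26 ± 0.15) and Sqle (0.22 ± 0.14) had its smallest p among higher members. The LXR and RORA target list had 5 of 17 members higher (median -0.21, adjusted p = 0.100). Lpcat3 (0.37 ± 0.18), Nr1h2 (0.19 ± 0.14), Apoe (-0.79 ± 0.19) and Abcg1 (-0.33 ± 0.16) had its smallest p in each direction. The nuclear oxidative phosphorylation list had 32 of 74 members higher (median -0.020, adjusted p = 0.723). Uqcrc1 (0.23 ± 0.15), Ndufv1 (0.25 ± 0.13), Atp5k (-0.35 ± 0.18) and Ndufa3 (-0.22 ± 0.14) had its smallest p in each direction. The mitochondrially encoded list had 8 of 13 members higher (median 0.075, adjusted p = 0.796; test direction lower). mt-Co1 (0.17 ± 0.17), mt-Atp6 (0.18 ± 0.18), mt-Nd2 (-0.22 ± 0.16) and mt-Nd3 (-0.38 ± 0.16) had its smallest p in each direction.

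Lists of excitability, release and axons between the diets were as follows. The sodium and calcium channel list had 12 of 26 members higher (median -0.0100, adjusted p = 0.723). Cacna2d3 (0.23 ± 0.16), Scn2b (0.19 ± 0.13), Cacna1a (-0.25 ± 0.17) and Scn4b (-0.35 ± 0.24) had its smallest p in each direction. The potassium channel list had 13 of 39 members higher (median -0.092, adjusted p = 0.331). Kcnip4 (0.29 ± 0.17), Kcnc2 (0.28 ± 0.15), Kcnk2 (-0.24 ± 0.16) and Kcnq3 (-0.33 ± 0.19) had its smallest p in each direction. The synaptic release list had 13 of 38 members higher (median -0.057, adjusted p = 0.239). Atp6v0c (0.75 ± 0.49), Vamp1 (-0.37 ± 0.27) and Sv2b (-0.39 ± 0.25) were among the members with its smallest p in each direction. The mechanotransduction list had 6 of 14 members higher (median -0.080, adjusted p = 0.678). Trpc6 (0.68 ± 0.32), Kcnk4 (0.49 ± 0.30), Kcnk2 (-0.24 ± 0.16) and Asic2 (-0.20 ± 0.14) had its smallest p in each direction. The neuropeptide and receptor list had 18 of 23 members higher (median 0.057, adjusted p = 0.239). Nppb (0.56 ± 0.29), Cck (0.91 ± 0.50), Ntrk2 (-0.38 ± 0.15) and Gfra3 (-0.16 ± 0.19) had its smallest p in each direction. The axon injury list had 14 of 20 members higher (median 0.056, adjusted p = 0.281). Plaur (0.85 ± 0.27), Nts (0.35 ± 0.20), Stmn4 (-0.22 ± 0.16) and Klf6 (-0.21 ± 0.12) had its smallest p in each direction. The cytoskeleton list had 13 of 37 members higher (median -0.033, adjusted p = 0.857). Tuba1a (0.26 ± 0.15), Prph (0.21 ± 0.13), Sptan1 (-0.24 ± 0.14) and Stmn4 (-0.22 ± 0.16) had its smallest p in each direction.

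The remaining lists between the diets did not pass either. The heat shock list had 6 of 15 members higher (median -0.066, adjusted p = 0.281). Hspa8 (0.22 ± 0.13), Hsp90ab1 (0.11 ± 0.12), Cryab (-0.43 ± 0.24) and Hspa1b (-0.54 ± 0.17) had its smallest p in each direction. The endoplasmic reticulum stress list had 12 of 23 members higher (median 0.0048, adjusted p = 0.758). Asns (0.23 ± 0.16), Pdia6 (0.26 ± 0.19), Hspa5 (-0.20 ± 0.16) and Pdia4 (-0.19 ± 0.20) had its smallest p in each direction. The myelin list had 5 of 11 members higher (median -0.034, adjusted p = 0.331). Ugt8a (0.67 ± 0.51), Pmp22 (0.16 ± 0.14) and Prx (-1.25 ± 0.73) were among the members with its smallest p in each direction. The inflammation list had 9 of 20 members higher (median -0.0075, adjusted p = 0.987). Ccl2 (0.46 ± 0.17), Ifit3 (0.46 ± 0.26), Ifitm3 (-0.65 ± 0.20) and Ccl4 (-3.21 ± 0.64) had its smallest p in each direction. The ribosomal protein list had 35 of 50 members higher (median 0.026, adjusted p = 0.239). Rpl4 (0.24 ± 0.15), Rpl3 (0.25 ± 0.14), Rpl35 (-0.21 ± 0.17) and Rpl38 (-0.33 ± 0.23) had its smallest p in each direction.

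In supplemented against wild type mice, Necab1 rose in NP3-like neurons, globin transcripts and Wdfy1 rose in PEP-like neurons, and Pam, Fabp7 and Apoe rose in NP1-like and NP2-like neurons. Over the 7 classes edgeR made 30 calls in 5 classes, 29 higher and 1 lower, in 23 distinct genes, beside 28 with DESeq2 and 25 with limma-voom. Necab1 was again higher in NP3-like neurons (3.47 ± 0.39, adjusted p = 8.94e-06; 80 against 9 UMIs), as were Hba-a1 (4.13 ± 0.37, adjusted p = 2.00e-06), Hbb-bs (4.09 ± 0.38, adjusted p = 2.51e-06) and Hba-a2 (2.16 ± 0.26, adjusted p = 8.60e-05) in PEP-like neurons, and these calls held under the 14 alternatives run for classes. Hbb-bt had 76 against 1 UMIs, a ratio of 112 with a counting interval of 19.4 to 4462. All neurons, PEP-like included, had 4 of 4 erythroid-like markers higher (median 2.62). Wdfy1 was higher in PEP-like (1.57 ± 0.22, adjusted p = 6.61e-04) and NP1-like neurons (1.33 ± 0.25, adjusted p = 0.0334), calls that ended when 1 mouse was left out in PEP-like (adjusted p = 0.0887 without 671 and 0.0731 without 699) and in NP1-like neurons (0.318 without 671, 0.280 without 698 and 0.180 without 699; also with DESeq2, with limma-voom, with doublets kept). Gpm6b (chromosome X), a proteolipid family gene of neurons and glia, was higher in PEP-like neurons (0.93 ± 0.17, adjusted p = 0.0448), a call that ended in the same way (adjusted p = 0.206 without 670, 0.693 without 671 and 0.454 without 699; also with DESeq2, with doublets kept, with both diets as 1 group).

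Pam was higher in supplemented NP2-like (1.46 ± 0.19, adjusted p = 5.91e-05) and NP1-like neurons (1.01 ± 0.16, adjusted p = 0.00773), as were Fabp7 (1.74 ± 0.26, adjusted p = 4.69e-04 and 1.27 ± 0.19, adjusted p = 0.00392) and Apoe (1.16 ± 0.19, adjusted p = 0.00155 and 1.0 ± 0.15, adjusted p = 0.00392). The Pam call in NP2-like neurons held under those 14 alternatives. Others ended when 1 mouse was left out: Pam in NP1-like (adjusted p = 0.181 without 671, 0.0817 without 698 and 0.0862 without 699), Fabp7 in NP2-like (0.170 without 671 and 0.0717 without 698; also with both diets as 1 group) and NP1-like (0.109 without 671 and 0.0809 without 698; also with both diets as 1 group) and Apoe in NP2-like neurons (0.0541 without 671 and 0.182 without 698; also with both diets as 1 group). Satellite-glia-like markers in all neurons moved the same way (10 of 10 higher, median 0.80). In NP1-like neurons Rbm15 (1.13 ± 0.20, adjusted p = 0.0233) and Rpgrip1 (chromosome 14; 1.0 ± 0.18, adjusted p = 0.0269) also rose, with the calls ending for Rbm15 (0.234 without 671, 0.0733 without 698 and 0.187 without 699; also with doublets kept) and Rpgrip1 (0.0504 without 670, 0.145 without 671, 0.388 without 698 and 0.0539 without 699; also with doublets kept). Further calls in NP1-like neurons were Actb (0.72 ± 0.10) and Abhd2 (0.92 ± 0.14), each with an adjusted p of 0.00392, the G protein subunit gene Gnb1 (chromosome 4, 155491361 to 155559269; 0.62 ± 0.11, adjusted p = 0.0175), Marf1 (chromosome 16; 0.79 ± 0.15, adjusted p = 0.0334) and the lipid phosphatase gene Inpp4a (chromosome 1; 0.76 ± 0.15, adjusted p = 0.0386). In NP2-like neurons Actb rose (0.96 ± 0.17, adjusted p = 0.00827). The lipid hydrolase gene Abhd2 (chromosome 7, 0.99 ± 0.20, adjusted p = 0.0220) also rose. So did the anion channel gene Lrrc8a (chromosome 2, 0.96 ± 0.20, adjusted p = 0.0398). Abhd2 lost its call without 671, 698 or 699, with sex or doublets kept. Lrrc8a did without 670, 671, 698 or 699, with DESeq2 or sex, and without the shallowest libraries. Actb in both classes and Apoe, Abhd2, Gnb1, Marf1 and Inpp4a in NP1-like neurons were not followed and may not hold.

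In satellite-glia-like cells of supplemented against wild type mice, the myelin basic protein gene Mbp (chromosome 18; 1.71 ± 0.40, adjusted p = 0.0482) was higher. The translation factor gene Eef1a2 (chromosome 2; 1.32 ± 0.29, adjusted p = 0.0369) and the small heat shock protein gene Cryab (chromosome 9; 1.52 ± 0.36, adjusted p = 0.0482) were also higher. The cannabinoid receptor gene Cnr1 (chromosome 4, 33924593 to 33948831), 13.9 Mb from Ttpa, was lower (-1.70 ± 0.41, adjusted p = 0.0482). These 4 calls ended without mouse 670, with a log2 fold change of 0.25 for Mbp (adjusted p = 1), 1.22 for Eef1a2 (0.533), 0.99 for Cryab (1) and -1.57 for Cnr1 (0.899). Mbp stood at 686 and 148 against 130 and 119 CPM. The 4 calls also ended with DESeq2, with limma-voom, with doublets kept, without the shallowest libraries and with both diets as 1 group. With RLE factors Mbp, Cryab and Cnr1 ended, and Cnr1 did without the filter. Mbp (adjusted p = 0.0757), Eef1a2 (0.858) and Cryab (0.993, log2 fold change 0.71) also lost their call without 698, and Cnr1 did without 671 (0.161), 698 (0.272) and 699 (0.152). The class total was 85 without mouse 654, 91 without 657, 73 without 670 and 45 without 671. In the unnamed cluster 18 Fabp7 (1.72, adjusted p = 0.00293; 252 and 923 against 247 and 101 CPM) and Apoe (1.48, adjusted p = 0.0151; 504 and 2128 against 681 and 251 CPM) were higher in group means, mainly through 671, and Apoe in 670 was below that in 698.

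TH-like and NF-like neurons had 0 calls with edgeR and limma-voom between supplemented and wild type mice (322 and 397 genes with an unadjusted p under 0.05 with edgeR), and DESeq2 called 3 and 0. With edgeR TH-like neurons had 21, 22, 12 and 1 without 654, 657, 670 and 699, and NF-like neurons 10, 9, 9 and 16 without 654, 657, 670 and 671. Smallest p values that did not pass were, in NF-like neurons, Slitrk2 (2.18 ± 0.39), Wdfy1 (1.64 ± 0.31), Malat1 (1.28 ± 0.25, adjusted p = 0.137), Abhd2 (0.84 ± 0.18) and Hsf2 (0.88 ± 0.19, adjusted p = 0.202). In TH-like neurons they included Apoe (1.141 ± 0.21), Kdm6b (1.23 ± 0.23, adjusted p = 0.129), Gpm6b (1.139 ± 0.23) and Slc39a1 (1.38 ± 0.28, adjusted p = 0.152). In NP3-like neurons they included Car8 (-2.16 ± 0.47, adjusted p = 0.183) and Ndrg1 (1.69 ± 0.38). Summed over all neurons, edgeR and limma-voom called 0 genes (498 with an unadjusted p under 0.05 with edgeR, against 667 expected by chance) and DESeq2 14. Among the smallest p were those of Wdfy1 (1.47 ± 0.25), Slc39a1 (1.13 ± 0.20), Gm10600 (1.27 ± 0.22) and the stress-responsive gene Ndrg1 (1.145 ± 0.20), each with an adjusted p of 0.312. Without mouse 654 the count was 11, and without 657 or 670 it was 1. Marker sets in neurons were myelinating Schwann-like (8 of 8 higher, median 0.62) and non-myelinating Schwann-like (6 of 8 higher, median 0.15). Fibroblast-like (5 of 7 higher, median 1.33), endothelial-like (5 of 7 higher, median 0.33), mural-like (3 of 4 higher, median 0.96), and proliferating (1 of 4 higher, median -0.34) markers were also measured. Neuron sets were NP1-like (9 of 9 higher, median 0.45), NF-like (4 of 16 higher, median -0.19), PEP-like (4 of 11 higher, median -0.22), NP2-like (2 of 5 higher, median -0.018), NP3-like (2 of 8 higher, median -0.071), TH-like (2 of 8 higher, median -0.17), TRPM8-like (3 of 4 higher, median 0.22) and pan-neuronal (7 of 13 higher, median 0.00076).

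Of the 20 lists, 5 passed in supplemented against wild type neurons at the preset correlation, and 0 with an estimated correlation (adjusted p = 0.901 for the ribosomal list and 0.818 for the other 4) or with fry. At the preset correlation the mitochondrially encoded list tested lower (median -0.42, 0 of 13 higher, adjusted p = 7.15e-09), with mt-Nd6 (0.048 ± 0.24), mt-Co2 (-0.43 ± 0.15) and mt-Atp6 (-0.53 ± 0.18). Median mitochondrial shares were 2.61% and 3.55% in the supplemented libraries against 4.80% and 3.97%. The ribosomal list tested lower (median -0.13, 6 of 50 higher, adjusted p = 1.78e-05), with Rps19 (0.032 ± 0.13), Rpl38 (0.010 ± 0.23), Rpl7 (-0.22 ± 0.15) and Rps24 (-0.28 ± 0.17). The myelin list tested higher (median 0.58, 10 of 11 higher, adjusted p = 1.78e-05) beside the myelinating Schwann-like markers (8 of 8 higher, median 0.62), with Prx (2.62 ± 0.84). The cholesterol list tested higher (median 0.092, 20 of 25 higher, adjusted p = 0.00818), with Insig1 (0.48 ± 0.14), Nsdhl (-0.069 ± 0.13) and Sqle (-0.11 ± 0.14). The inflammation list tested higher (median 0.14, 14 of 20 higher, adjusted p = 0.0102) beside macrophage-like markers (3 of 4 higher, median 0.43) and a macrophage-like share higher in both supplemented than in both wild type mice, with Ifitm3 (0.94 ± 0.21), Ccl4 (2.66 ± 0.58), Il6 (-0.92 ± 0.47) and Ccl2 (-0.62 ± 0.17). Ccl4 is among the 10 leading genes of the macrophage-like and Ifitm3 among those of the endothelial-like cluster. The count of lists was 8 without mouse 698 and 3 without 670 or 699. The inflammation and ribosomal tests turned direction without 699. Adjusted over the list alone, 12 members passed, among them Apoe, Prx, Mrgprd, Ifitm3 and Ccl4 with higher values and Gal and Ccl2 with lower values.

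The other 15 lists did not pass in supplemented against wild type neurons. The vitamin E transport list had 10 of 15 members higher (median 0.11, adjusted p = 0.0615). Scarb1 (0.79 ± 0.27), Apoe (0.81 ± 0.19), Pltp (-0.30 ± 0.22) and Lpl (-0.45 ± 0.24) had its smallest p in each direction. The antioxidant and NRF2 target list had 14 of 33 members higher (median -0.027, adjusted p = 0.516). Sod3 (0.76 ± 0.51), Hmox1 (0.55 ± 0.16), Gstm1 (-0.33 ± 0.15) and Gpx3 (-0.40 ± 0.15) had its smallest p in each direction. The lipid peroxidation list had 10 of 20 members higher (median -0.023, adjusted p = 0.825; test direction higher). Aifm2 (0.69 ± 0.43), Scd1 (0.34 ± 0.16), Tfrc (-0.23 ± 0.13) and Fads2 (-0.69 ± 0.45) had its smallest p in each direction. The LXR and RORA target list had 11 of 17 members higher (median 0.075, adjusted p = 0.516). Apoe (0.81 ± 0.19), Mylip (0.53 ± 0.29), Nr1d2 (-0.30 ± 0.19) and Pcp4 (-0.44 ± 0.23) had its smallest p in each direction. The nuclear oxidative phosphorylation list had 34 of 74 members higher (median -0.0091, adjusted p = 0.584). Ndufc1 (0.14 ± 0.14), Atp5k (0.21 ± 0.18) and Atp5h (-0.14 ± 0.13) were among the members with its smallest p in each direction. The immediate early list had 12 of 22 members higher (median 0.029, adjusted p = 0.516). Zfp36 (0.51 ± 0.17), Nr4a1 (0.60 ± 0.22), Klf4 (-0.25 ± 0.19) and Ier3 (-0.13 ± 0.13) had its smallest p in each direction. The heat shock list had 6 of 15 members higher (median -0.0063, adjusted p = 0.965; mean 0.022, test direction lower). Hspa1b (0.25 ± 0.17), Hspa1a (0.46 ± 0.20), Hspb1 (-0.33 ± 0.17) and Hsp90aa1 (-0.15 ± 0.15) had its smallest p in each direction. The endoplasmic reticulum stress list had 15 of 23 members higher (median 0.043, adjusted p = 0.795). Atf5 (0.12 ± 0.14), Xbp1 (0.12 ± 0.14), Dnajb9 (-0.25 ± 0.15) and Atf4 (-0.091 ± 0.14) had its smallest p in each direction.

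Lists of excitability, release and axons in supplemented against wild type neurons were as follows. The sodium and calcium channel list had 12 of 26 members higher (median -0.0058, adjusted p = 0.825). Scn10a (0.19 ± 0.13), Scn11a (0.34 ± 0.21), Cacna1e (-0.55 ± 0.21) and Cacna2d3 (-0.23 ± 0.16) had its smallest p in each direction. The potassium channel list had 16 of 39 members higher (median -0.020, adjusted p = 0.584). Kcnmb4 (0.29 ± 0.17), Kcnma1 (0.34 ± 0.15), Kcns3 (-0.33 ± 0.14) and Kcnv1 (-0.49 ± 0.21) had its smallest p in each direction. The synaptic release list had 16 of 38 members higher (median -0.017, adjusted p = 0.825). Bsn (0.23 ± 0.13), Syt7 (0.36 ± 0.13), Snap25 (-0.39 ± 0.17) and Atp6v0c (-1.16 ± 0.46) had its smallest p in each direction. The mechanotransduction list had 10 of 14 members higher (median 0.073, adjusted p = 0.516). Asic2 (0.20 ± 0.14), Trpv4 (-0.24 ± 0.55) and Kcnk4 (-0.50 ± 0.30) were among the members with its smallest p in each direction. The neuropeptide and receptor list had 9 of 23 members higher (median -0.063, adjusted p = 0.584). Mrgprd (1.11 ± 0.25), Gfra2 (0.33 ± 0.16), Calca (-0.30 ± 0.16) and Gal (-0.50 ± 0.12) had its smallest p in each direction. The axon injury list had 10 of 20 members higher (median 0.00071, adjusted p = 0.584; test direction lower). Tubb2b (0.14 ± 0.13), Sdc1 (0.75 ± 0.22), Hspb1 (-0.33 ± 0.17) and Gal (-0.50 ± 0.12) had its smallest p in each direction. The cytoskeleton list had 18 of 37 members higher (median -0.021, adjusted p = 0.795). Kif1a (0.21 ± 0.14), Ina (0.19 ± 0.13), Map2 (-0.24 ± 0.17) and Stmn4 (-0.23 ± 0.16) had its smallest p in each direction.

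NF-like neurons were compared with all other neurons of the same mouse by an interaction with group over 12860 genes. edgeR and DESeq2 called 0 genes in all 3 contrasts, with 566, 435 and 547 genes at an unadjusted p under 0.05 with edgeR and 76, 54 and 92 with DESeq2 for deficient against wild type, deficient against supplemented and supplemented against wild type. In deficient against wild type mice the smallest p belonged to Tmem229b (0.81 ± 0.17, adjusted p = 0.486), Nts (-3.43 ± 0.80), Pcdh8 (-1.51 ± 0.36), Cd9 (-0.51 ± 0.13) and 1700086L19Rik (1.10 ± 0.28). Between the diets it belonged to Pvalb (1.39 ± 0.30, adjusted p = 0.534), Hbb-bt (-3.54 ± 0.88), Clec2l (0.67 ± 0.17), Negr1 (0.94 ± 0.25) and Aldoc (-0.58 ± 0.15). In supplemented against wild type mice it belonged to Malat1 (0.71 ± 0.15, adjusted p = 0.496), Pvalb (-1.24 ± 0.29), Nts (-3.08 ± 0.74), Wfdc2 (6.89 ± 1.67) and Stxbp6 (-2.79 ± 0.68). Without mouse 657 the deficient against wild type count was 36 and without 698 it was 10. The counts reached 7 between the diets without 654 and 7 in supplemented against wild type mice without 657.

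NP1-like cells made up 19.9% and 13.3% of the cells kept in deficient mice 654 and 657, 19.1% and 14.4% in supplemented mice 670 and 671 and 10.9% and 8.03% in wild type mice 698 and 699. The group means ± standard deviation were 16.6 ± 4.68%, 16.8 ± 3.36% and 9.48 ± 2.05%, differences of 7.12 and 7.28 points from wild type with an exact permutation p of 0.333, the lowest that 2 against 2 mice can reach. Genes leading NP1-like clusters include 9130204L05Rik (log2 1.498 in deficient and 0.60 in supplemented against wild type neurons, not passing) and Mrgprd (1.0 and 1.11, not passing). PEP-like cells were at 26.1%, 33.0%, 27.8%, 30.9%, 35.8% and 34.2% in mice 654, 657, 670, 671, 698 and 699, with group means of 29.5 ± 4.88%, 29.4 ± 2.22% and 35.0 ± 1.16%. In the same order of mice, NF-like cells were at 10.0%, 11.0%, 13.1%, 13.7%, 10.4% and 16.6%, NP2-like at 2.60%, 3.80%, 1.93%, 2.64%, 2.88% and 3.38% and NP3-like at 12.2%, 7.56%, 8.03%, 8.44%, 7.45% and 9.88%. TH-like cells were at 18.9%, 22.0%, 16.6%, 18.3%, 20.02% and 19.3% and TRPM8-like cells at 1.39%, 1.47%, 2.14%, 1.63%, 1.83% and 0.569%. Satellite-glia-like cells were at 2.10%, 0.752%, 3.69%, 2.89%, 2.52% and 1.02%, macrophage-like cells at 0.783%, 0.0358%, 1.17%, 0.409%, 0.240% and 0.210% and endothelial-like cells at 0.177%, 0.107%, 0.0763%, 0.163%, 0.210% and 0.299%. Differences between groups in satellite-glia-like and TH-like shares are not read as changes, since genes that differ between groups, such as Pam, lead clusters of those classes. Unnamed cluster 9 was at 4.62%, 5.59%, 5.19%, 5.09%, 4.59% and 4.67% and cluster 18 at 1.11%, 1.43%, 1.144%, 1.33%, 3.09% and 1.77%.

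**Figure D2:**
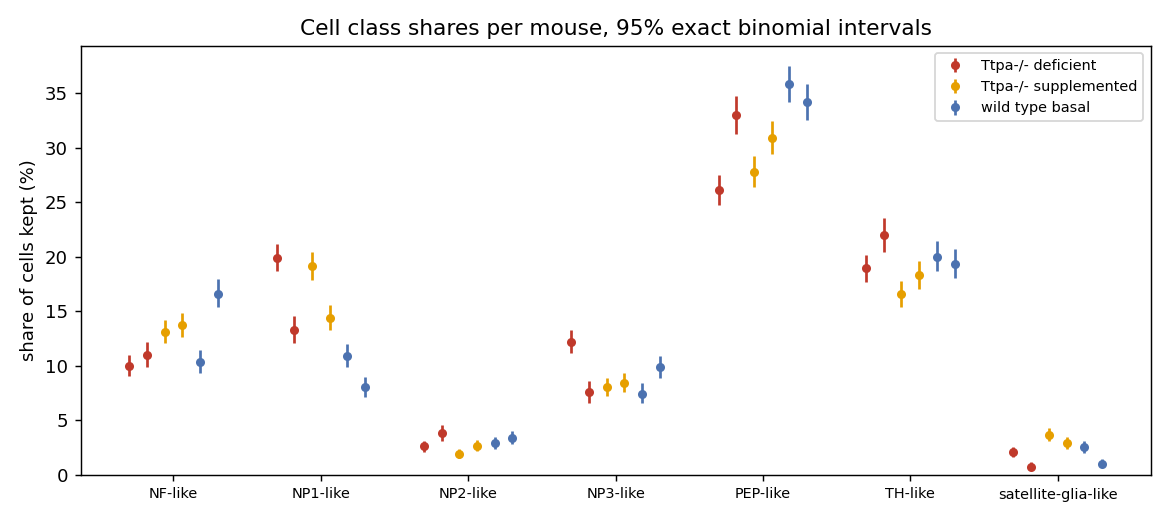
Share of kept cells per mouse in 7 cell classes. Bars are 95% exact binomial intervals for each mouse.

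The contrasts of deficient mice with wild type and with supplemented mice share the 2 deficient libraries. No gene was called in both. At an unadjusted p under 0.05, 17 genes were higher in both (278 and 122 genes) and 32 lower in both (238 and 186), against 2.54 and 3.3202 from the product of the 2 counts over the genes tested. Unchanged groups sharing libraries gave means of 57.7 and 73.5 such genes in 100 simulations (highest 76 and 98) and 0.43 and 0.40 shared calls. The observed 17 and 32 exceed the product. The data held fewer such p than chance gives, so these means cannot judge them.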

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

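The tests of position near Ttpa, of chromosomes, of diet, of glial RNA across markers, of calls over 20 draws and of the NP1-like share at a common UMI minimum were chosen only after results were seen; the tests of depth in 1 draw, of droplets with whole glial cells and of Mrgprd at a fixed depth were written before their values were computed. Of the genes called between genotypes in cell classes, DNA carried along with the targeted locus could account for Necab1, Car8 and Cnr1, since 3 of 27 called genes (11.1%) lie within 20 Mb of Ttpa against 0.730% of the 11650 genes tested in classes, a difference prompted by these genes. With called genes left out, genes within 20 Mb were not set apart (Fisher exact p = 0.174, open; 0.0148 with them), and windows of 10 Mb, 40 Mb and the whole chromosome gave 0.0418, 0.734 and 0.524. The 22 called genes on other chromosomes argue against linked DNA for those. Thinning each class to its smallest UMI sum left a median of 0.994 of the fold over the 47 calls measured (Cnr1 was not), which argues against depth for these folds as a set. That was 1 draw, in which 37 were still called and 10 ended with wider standard errors on fewer UMIs. Over 20 draws 24 of the 47 were called in every draw, 36 in over 10 and 11 in 10 or fewer, 2 of these in 0. In the 1st draw all 5 calls of deficient against wild type mice in NP2-like neurons ended, with Pam moving from 1.11 ± 0.19 to 0.96 ± 0.22, Tmf1 from 1.20 ± 0.24 to 1.24 ± 0.32, Rbm15 from 1.97 ± 0.40 to 0.95 ± 0.69, Bhlhe41 from 0.91 ± 0.19 to 0.89 ± 0.20 and Actb from 0.84 ± 0.17 to 0.84 ± 0.19. Wdfy1 in NF-like neurons moved from 2.16 ± 0.30 to 2.02 ± 0.36, with a call in 11 of 20 draws. In supplemented against wild type mice Fabp7 moved from 1.74 ± 0.26 to 1.33 ± 0.32 and Lrrc8a from 0.96 ± 0.20 to 0.87 ± 0.24 in NP2-like neurons, and Eef1a2 from 1.32 ± 0.29 to 1.52 ± 0.43 and Cryab from 1.52 ± 0.36 to 1.16 ± 0.60 in satellite-glia-like cells. Over the draws Fabp7 was called in 16, Pam in 11, Tmf1 and Bhlhe41 in 7 each, Actb and Lrrc8a in 5 each and Eef1a2 in 1, while Gpm6b in PEP-like neurons and Mbp in satellite-glia-like cells, still called in the 1st draw, were called in 6 and 3. A median of 0.917 of the Rbm15 fold was left (log2 fold change 0.95 to 3.46, called in 0 draws). For Cryab it was 0.727 (0.83 to 1.79, called in 0). In genes other than Car8, 16 calls were made between deficient and wild type mice. Their diet fold was a median of 0.0280 of the genotype fold (upper quartile 0.179). Vitamin E was not measured, so its status stays open. Genes called only in other contrasts, such as Apoe and Fabp7 between the diets, were not part of the diet test. Car8 stayed open, with the lower supplemented value at 0.887 of the higher deficient value and mouse 670 at 10.5 times it. Strain, age and basal diet go with genotype and stay open for all of these genes.

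Another pattern was Apoe and Fabp7, higher in NP1-like and NP2-like neurons of supplemented than of wild type mice. RNA of satellite glia in neuron droplets stayed open. Across the 8 markers other than Apoe and Fabp7, the excess in neurons against the level in satellite-glia-like cells had a Spearman rho of 0.476 (permutation p = 0.243, across genes that are not independent), with 7 of 8 higher in supplemented mice and Glul 7.33 CPM lower. Apoe had 112 CPM of excess against 3477 in the glia and Fabp7 56.5 against 1186. Droplets with a whole glial cell also stayed open. In neurons with no UMI of the other markers (687 of 1454 supplemented and 329 of 841 wild type cells) both genes fell. Apoe went from 225 and 113 to 123 and 46.1 CPM. It kept 1.42 of its log2 ratio and Fabp7 1.22. A change within neurons was not separated from glial RNA.

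The last pattern was the NP1-like share, higher in all Ttpa-/- mice. A UMI minimum that differs between libraries stayed open: with 1985 UMIs or more in every library the shares were 25.2%, 13.3%, 25.7%, 16.5%, 12.3% and 8.27% in mice 654, 657, 670, 671, 698 and 699, and the lowest Ttpa-/- share (counting interval 12.1 to 14.6) was 1.02 points above the highest wild type share (11.1 to 13.5), with overlapping intervals. A test written before, among cells at or above the median of their mouse (lowest Ttpa-/- share 22.1%, highest wild type share 18.2%, intervals apart), is not used, since it set no common minimum and multiplied every share by 1.53 to 1.77. Cluster borders set by genes that differ between genotypes also stayed open: at 1000 UMIs per cell the share of cells with 2 or more Mrgprd UMIs was 0.354%, 0.215%, 0.289%, 0.272%, 0.0901% and 0.0299% in mice 654, 657, 670, 671, 698 and 699, a gap of 0.125 points from 14, 6, 11, 10, 3 and 1 cells with overlapping intervals. NF-like neurons, as a background, had 0%, at median depths of 3356, 7994, 3075, 5464, 6263 and 7685 UMIs against 5069, 10062, 4593, 6480, 8612.5 and 8773 in NP1-like neurons, and 133 cells of mouse 670 under 1000 UMIs were left out.

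Shares that differed in opposite directions in females and males are listed next; female and male are 1 mouse each per group and these differences were not tested. The female minus male difference in supplemented against wild type mice was 6.85 points for NF-like cells (3.34 in females, -3.51 in males). NP1-like cells had 11.4 points between the diets (5.53 and -5.85), and PEP-like cells -10.04 (-4.85 and 5.19). NP2-like cells had -0.693 in deficient against wild type mice (-0.280 and 0.414) and -1.91 between the diets (-0.0400 and 1.87). NP3-like cells had 7.11 in deficient against wild type mice (4.78 and -2.32), 4.26 between the diets (3.78 and -0.473) and 2.85 in supplemented against wild type mice (0.999 and -1.85). TH-like cells had -3.69 in deficient against wild type mice (-1.08 and 2.62). TRPM8-like cells had -1.34 in deficient (-0.442 and 0.900) and -1.76 in supplemented against wild type mice (-0.197 and 1.57). Macrophage-like cells had 0.717 in deficient against wild type mice (0.543 and -0.174) and 1.51 between the diets (0.375 and -1.13).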

How the results depend on the processing

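The alternatives without the shallowest libraries and with both diets as 1 group were chosen only after results were seen. Mouse numbers pair no mice across groups, and sex, with 1 female and 1 male per group, was fitted as a term. Each leave-out leaves a group with 1 mouse, whose spread is assumed to equal that of the other groups, and depth limits the test to genes with enough counts (the shallowest neuron sum held 11821486 UMIs). Of single-gene folds followed through the alternatives, 4245 kept their direction and side of the threshold, 143 lost their call, 56 gained 1 and 75 turned sign. Of list tests, 80 kept their direction and call, 48 lost their call and 4 turned direction. The cause of each move below was not tested except where fewer mice were used.

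In neurons, deficient against wild type, deficient against supplemented and supplemented against wild type calls were 72, 18 and 116 without the low-count filter, which widens the set of genes that share a spread. DESeq2 gave 2 in the 1st and 14 in the last contrast, sex as a term 1 in the 1st, a matched class mix 3 and 9 in the 1st and last, and leaving out the shallowest library of each Ttpa-/- group 2 and 4 in these. Leave-outs gave 0 to 1, 0 to 1 and 0 to 11. Over the classes the same 3 contrasts gave 80, 60 and 236 without the filter, 34, 82 and 155 without the shallowest libraries, 11 with DESeq2 and 30 with both diets as 1 group in the 1st, 9 and 60 with sex in the 2nd and last, and 17 with doublets kept in the last. Leave-outs gave 11 to 43, 6 to 19 and 28 to 91. The interaction gave 6, 3 and 9 without the filter and 0 to 36, 0 to 7 and 0 to 7 over leave-outs. Lists gave 0 with an estimated correlation and 0 with fry, 1 to 10, 1 to 4 and 3 to 8 over leave-outs, 3 in the 1st contrast without the shallowest libraries, and 3 with sex and 2 with a matched mix between the diets. The overlap of calls was 0 to 1 over leave-outs. Differences in shares moved by more than the standard deviation between mice for NF-like cells between the diets (from -2.91 to -4.25 points with the stricter filter), PEP-like (from -5.65 to -9.23 with the stricter filter, -3.19 at resolution 0.5) and TH-like cells in supplemented against wild type mice (from -2.23 to -1.01 with the stricter filter, -3.21 at resolution 2) and endothelial-like cells in deficient against wild type mice (from -0.113 to -0.0560 at resolution 2). Satellite-glia-like cells moved from -1.86 to -0.694 (stricter filter) and -4.08 (resolution 2) between the diets and from 1.52 to -0.237 and 4.04 in supplemented against wild type mice. Those of TH-like and satellite-glia-like cells are given only as values. At resolution 0.5 a cluster of 1481 cells with 7 PEP-like markers stayed unnamed by the naming rule and is not in the PEP-like share there. Other alternatives changed no other sum of calls by more than 1.5 times and moved no other difference in shares by more than that standard deviation. Leaving out 699 turned the test of 2 lists, with medians over leave-outs of 0.016 to 0.37 (inflammation) and -0.21 to 0.050 (ribosomal) in deficient and 0.0023 to 0.33 and -0.27 to -0.0084 in supplemented against wild type neurons. Without 699 they were 0.016, 0.050, 0.11, -0.0084 in that order, so the direction of these tests turned and the median changed sign for the ribosomal list in deficient against wild type neurons.

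Signs turned with a matched class mix for Scarb1 -0.00069, Kcnip4 -0.029, Unc13c -0.12, Kcnk2 0.041, Gal 0.072, Map2 0.010, Egr2 0.077, Rps9 -0.012 (deficient against wild type), Jund -0.031 (deficient against supplemented), Trpv4 0.20 (supplemented against wild type). Signs turned without the shallowest libraries for Npc1 -0.13, Hsd17b7 0.00100, Scn11a -0.035, Atf3 -0.026, Nr4a1 -0.17, Hspa1a -0.072 (deficient against wild type), Nts -0.018, Jund -0.044, Nppb -0.33, Gfra3 0.026 (deficient against supplemented). Signs turned with both diets against wild type for Acsl4 0.0056, Egr2 0.24 (deficient against wild type), Nsdhl 0.0046, mt-Nd6 -0.042, Hspa1b -0.022, Rpl38 -0.15 (supplemented against wild type). Signs turned with doublets kept for Egr2 0.036 (deficient against wild type). Signs turned with the stricter filter for Egr2 0.050 (deficient against wild type), mt-Nd6 -0.0078 (supplemented against wild type). Signs turned after thinning for Pllp 0.095 (deficient against wild type), mt-Nd6 -0.011 (supplemented against wild type). Signs turned with limma-voom for mt-Nd6 -0.013 (supplemented against wild type). Signs turned with all cells for Rpl38 -0.0038 (supplemented against wild type). For turns without 1 mouse, the range over all 6 leave-outs is given at first mention. Leaving out 654 turned Npc1 -0.13 to 0.47, Hsd17b7 -0.23 to 0.00062, Scn11a -0.035 to 0.59, Atf3 -0.026 to 0.18, Nr4a1 -0.17 to 0.50, Hspa1a -0.091 to 0.46 (deficient against wild type), Nts -0.070 to 0.67, Jund -0.11 to 0.18, Nppb -0.20 to 1.05 (deficient against supplemented), Rpl38 -0.33 to 0.42 (supplemented against wild type). Leaving out 657 turned Egr2 -0.40 to 0.33, Pllp -0.44 to 0.11 (deficient against wild type), mt-Co1 -0.083 to 0.39, mt-Atp6 -0.063 to 0.38 (deficient against supplemented). Leaving out 670 turned Gfra3 -0.33 to 0.014 (deficient against supplemented). Leaving out 671 turned mt-Nd2 -0.41 to 0.010, Jund, Pdia4 -0.50 to 0.21, Rpl35 -0.42 to 0.035 (deficient against supplemented), Nsdhl -0.18 to 0.017, mt-Nd6 -0.53 to 0.43, Rps19 -0.074 to 0.13, Rpl38 (supplemented against wild type). Leaving out 698 turned Cyp51 -0.24 to 0.067, Pllp, Il6 -0.94 to 0.65, Ccl2 -0.38 to 0.076, Rpl3 -0.026 to 0.27 (deficient against wild type), Sqle -0.29 to 0.075, Atp5k -0.028 to 0.48, mt-Nd6, Trpv4 -0.84 to 0.66, Hsp90aa1 -0.35 to 0.053, Il6 -1.52 to 0.063, Rps19, Rpl38 (supplemented against wild type). Leaving out 699 turned Ndufa9 -0.0022 to 0.40, Asic3 -1.02 to 0.14, Hspa1a, Egr2 (deficient against wild type), Xbp1 -0.019 to 0.26, Atf4 -0.26 to 0.078 (supplemented against wild type).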

Other observations

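With both Ttpa-/- diets taken as 1 group of 4 mice against wild type, an alternative chosen only after results were seen, 30 calls were made over the 7 classes. The Wdfy1 call in NF-like neurons was kept there (1.90 ± 0.28, adjusted p = 0.00645) as was that in NP1-like neurons (1.5 ± 0.23, adjusted p = 0.0142). Of 39 class calls followed through the 14 alternatives run for classes (13 between the diets), 9 ended under none and 30 under at least 1.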
